A study of Zea mays with 48 samples.

How the data were processed

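Total RNA of maize leaf 5 was measured on 1-colour Agilent arrays (Cy3) in 12 groups, per the labels. Leaves of 21-day-old plants stood in water or in 5 µM peptide solutions for 12 h through the night, and each biological sample pooled 2 leaves. The labels list 48 arrays, 4 per group. The authors left out 3 of them after outlier detection with arrayQualityMetrics, per the labels: water replicate 4, ZmPep3 replicate 1 and ZmPep4d replicate 4.

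The deposited values are log2 signals that the authors had smoothed-quantile normalized, per the file headers and the name of the table; the log2 scale itself is read from the range of the values, 2.58 to 19.3. The submitters' processing notes name limma. The background correction and any filter on probes are not given in the sources used here. Of 2 deposited tables, the same 42034 probes and 45 arrays were compared and differed by at most 5e-09, so 1 of them was used. Each group was found to have its own distribution, so the groups still differed in distribution after the normalization. Signal over background per probe is not given in the sources used here, so dim probes could not be told from probes with no signal.

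Probes carry only the array's identifiers. Of these, 0 were found in the table of 49888 maize genes of the assembly Zm-B73-REFERENCE-NAM-5.0, so no probe was given a gene name, and the 26 gene lists written before the data were examined could not be used. The rule for named genes asked for probes with a gene name. In its place, the 2 probes with the largest rise and 2 with a large fall in the peptides together, by deposited log2 fold change among those past the threshold, are named by identifier. The pair with the largest falls had a bright signal on 1 water array alone, more than 2 log2 units above the other water arrays, and the next 2 in order were taken, a choice made after their values were seen.

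All tests used limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to the 45 arrays for each probe (lmFit), variances were moderated (eBayes), and p-values were adjusted by the Benjamini-Hochberg method over the 42034 probes within a contrast. A probe was called at an adjusted p under 0.05. All tests are two-sided. The contrasts were the mean of the 11 peptide groups minus water, each peptide minus water, 10 pairs of peptides, and ZmPep4all and ZmPep5all minus the mean of their lettered groups; the 11 peptide means were compared with a moderated F-test. The groups, tests and alternatives were fixed before the data were examined. Full quantile normalization (normalizeQuantiles) was among these alternatives. Giving its count beside each deposited count, with the other alternatives repeated on it, was chosen after seeing the data. Folds are 2 to the power of the log2 fold change, and intervals cover 95%.

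The other alternatives were the replicate number as a block, arrays centred on their medians, the dimmer 50% of the probes left out, a variance trend with robust moderation, only the groups compared in the fit, an absolute log2 fold change of at least 1, and each array left out in turn. For results over all peptides, each water array and all arrays of each replicate number were left out in turn. Shared fold changes were set beside 20 simulations of unchanged groups against the same water arrays. Other splits of the same arrays, up to 100 per contrast, were refitted in the same way.

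The fit was tested on simulated data for ZmPep1 against water over 42034 probes. With equal group distributions it recovered 83.6% of probes changed by 0.5 log2 units, 97% of those changed by 1 and 100% of those changed by 2. Once each simulated group had been mapped to its deposited distribution, 23817 probes were called, and 23629 of them had not been changed. After full quantile normalization of those values, 188 were called, 8 of them unchanged, with recovery of 77.6%, 92.5% and 100%. Only 67, 67 and 66 probes had been changed at these sizes. In the real ZmPep1 comparison 14221 probes were called after full quantile normalization. The simulation thus does not show how that step acts when many probes change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.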

Results

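Transcript levels were measured in leaves of maize (Zea mays) that had stood for 12 h in water or in a solution of plant elicitor peptides. These peptides, called ZmPeps in maize, are short signalling molecules that a plant releases from its own precursor proteins when it is wounded or attacked. Leaf 5 of 21-day-old plants was cut off and placed in a vial, and the peptide solutions were 5 µM. Each sample pooled 2 leaves. There were 12 groups: water, ZmPep1, ZmPep2, ZmPep3, ZmPep4a, ZmPep4b, ZmPep4c, ZmPep4d, ZmPep5a, ZmPep5b, and 2 groups called ZmPep4all and ZmPep5all, whose composition the labels do not state. The labels give 4 biological replicates per treatment. The authors removed 3 arrays as outliers, which left 3 arrays each for water, ZmPep3 and ZmPep4d and 4 for each of the other groups, 45 in all. Signals of 42034 probes were read on 1-colour Agilent arrays, and the number of arrays limits the precision of every value. Correlations across probes between arrays of the same group ran from 0.984 to 0.997 over 63 pairs, and no 2 arrays of a group were identical. Probes are not independent replicates, so these correlations only describe the arrays.

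The deposited values held 1 distribution per group. The lower quartile of the log2 signal was 6.91 ± 0.00163 (SD, n = 3) in water, 7.32 ± 0.000483 (SD, n = 3) in ZmPep3 and 6.33 ± 0.00406 (SD, n = 3) in ZmPep4d, and the SD within a group was at most 0.00591. Against water, the median log2 fold change over all probes was -0.29 in the peptides together, and it ran from -0.50 in ZmPep4d to 0.36 in ZmPep3. Because of these offsets, each count of probes is given on the deposited values and again after full quantile normalization, which gives all arrays 1 common distribution and leaves a median log2 fold change within 0.01 of 0 in each of these comparisons.

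**Figure D1:**
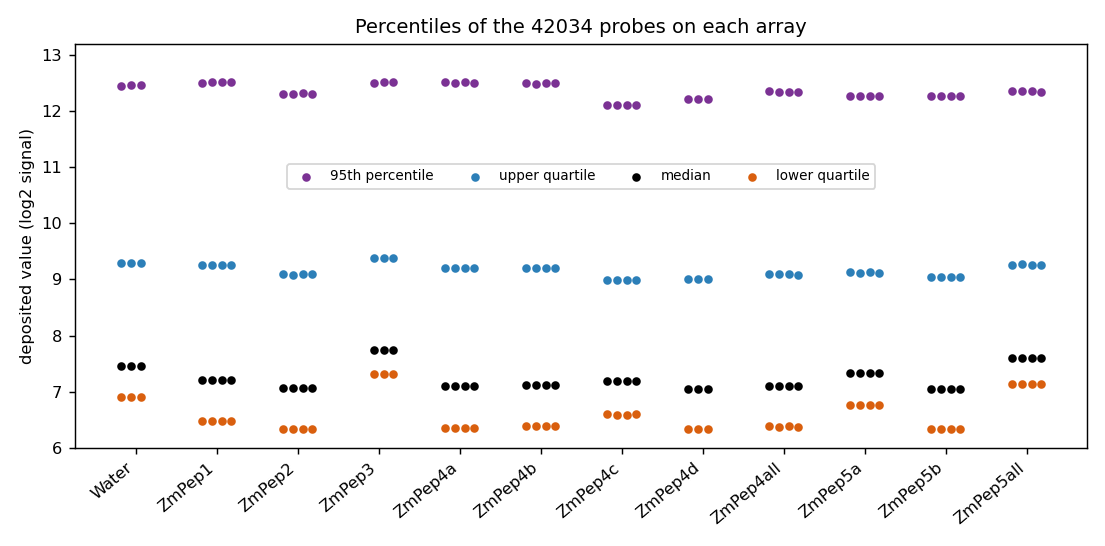
Each point is 1 array; the vertical axis gives the deposited log2 signal at the lower quartile, the median, the upper quartile and the 95th percentile of the 42034 probes, by group. Arrays of a group lie on top of each other, while the lower quartile of the groups ranges from 6.33 in ZmPep4d to 7.32 in ZmPep3.

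The comparison of all peptide groups with water asked which transcripts changed in leaves given any of the peptides. The largest rise was at probe A_92_P009308, whose mean signal over the 11 peptide groups lay 4.76 log2 units above water after full quantile normalization (SE 0.25, 95% interval 4.25 to 5.28, adjusted p = 2.7e-16) and 4.62 above it in the deposited values. On every peptide array this probe was brighter than on the water arrays, with 9.10 as the lowest peptide value and 8.65 as the highest water value. Probe A_92_P003953 rose by 4.52 log2 units (SE 0.35, adjusted p = 2.75e-12; 4.38 as deposited). Its size depended on single water arrays, which read 10.7, 12.0 and 9.52 (SD 1.23, n = 3) at this probe: the rise was 5.14 without water replicate 2 and 3.91 without water replicate 3 (4.99 and 3.78 as deposited). Probes A_92_P023385 and A_92_P035823 fell by 2.05 (SE 0.22, adjusted p = 6e-09) and 2.09 (SE 0.30, adjusted p = 1.36e-06) log2 units, with -2.18 and -2.17 as deposited. The table of maize genes used here holds none of the probe identifiers, so the genes behind these probes are not named.

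After full quantile normalization, 9868 probes passed an adjusted p of 0.05 in limma for the peptides together, 4533 higher and 5335 lower than water. The deposited values gave 33122 probes, 2129 higher and 30993 lower, and arrays centred on their medians gave 6606 higher and 14728 lower. Of the lower calls in the deposited values, 65.3% were in the dimmer 50% of the probes, and 17.2% were called lower again after full quantile normalization. Of the higher calls, 99.8% were called higher again. At 385 probes the direction was opposite between the 2 sets of calls. At least 2-fold changes were seen at 572 probes after full quantile normalization, 344 higher and 228 lower, and at 668 as deposited, 258 higher and 410 lower. Without the arrays of replicate number 1, the count after full quantile normalization was 6552.

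Each peptide was then set against water. By the counts after full quantile normalization, the probes that changed were most numerous in ZmPep1 and ZmPep3 and fewest in ZmPep5b. The order depended on the scaling: as deposited ZmPep4c had the most and ZmPep5a the fewest, and with arrays centred on their medians ZmPep1 had the most and ZmPep5a the fewest. Probe A_92_P009308 was 173-fold higher than water in ZmPep3, 106-fold in ZmPep4a, 99.9-fold in ZmPep1, 67.2-fold in ZmPep4all, 57.5-fold in ZmPep2, and 44.9-fold in ZmPep4b. In ZmPep4d its log2 fold change was 4.64 (SE 0.35, adjusted p = 9.52e-12). The rise of this probe was 8.20-fold in ZmPep5a, 6.68-fold in ZmPep5all and 6.62-fold in ZmPep4c. The ZmPep5a fold leaned on replicate 2. After full quantile normalization the ZmPep5a arrays read 11.26, 12.95, 10.62 and 10.78 (SD 1.07, n = 4). The order of these 3 groups at this probe is therefore uncertain. In ZmPep5b the log2 fold change of A_92_P009308 was 1.05 (SE 0.33, adjusted p = 0.126) after full quantile normalization. As deposited it was smaller, 0.79 (SE 0.32), yet passed (adjusted p = 0.0241). The adjusted p of a probe depends on the p-values of all probes. In this comparison 34036 passed as deposited, against 215 after full quantile normalization. A pass only as deposited, here or in later comparisons, is therefore no added evidence for a single probe. The other rising probe, A_92_P003953, was higher by 107-fold in ZmPep3 and 91.6-fold in ZmPep1, against 5.88-fold in ZmPep4c, and its log2 fold change in ZmPep5b was 1.37 (SE 0.44, adjusted p = 0.144; 0.017 as deposited). All folds of this probe rest on the same spread-out water arrays, and without water replicate 2 or 3 each of them moves by 1.54 or 1.52 times. For the other 3 named probes leaving out a water array moves the folds by at most 1.17 times. These values do not cover the spread between the arrays of a peptide group.

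The falling probes changed by smaller folds. A_92_P023385 was 11.7-fold lower than water in ZmPep3, 9.55-fold in ZmPep1, 7.24-fold in ZmPep4a and 2.22-fold in ZmPep5a. Its log2 fold change was -0.91 in ZmPep4c (adjusted p = 0.0567) and -0.68 in ZmPep5b (adjusted p = 0.289), while both passed the test as deposited (adjusted p = 0.000145 and 0.00421). A_92_P035823 was 11.4-fold lower in ZmPep3, 9.24-fold in ZmPep4all and 6.75-fold in ZmPep1. Its log2 fold changes in ZmPep4c, ZmPep5a and ZmPep5b were -1.01, -1.17 and -0.99 after full quantile normalization (adjusted p = 0.12, 0.0582 and 0.251) and passed the test as deposited (adjusted p = 0.00216, 0.00606 and 0.00683). All folds and log2 fold changes in this comparison are after full quantile normalization unless another basis is given.

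**Figure D2:**
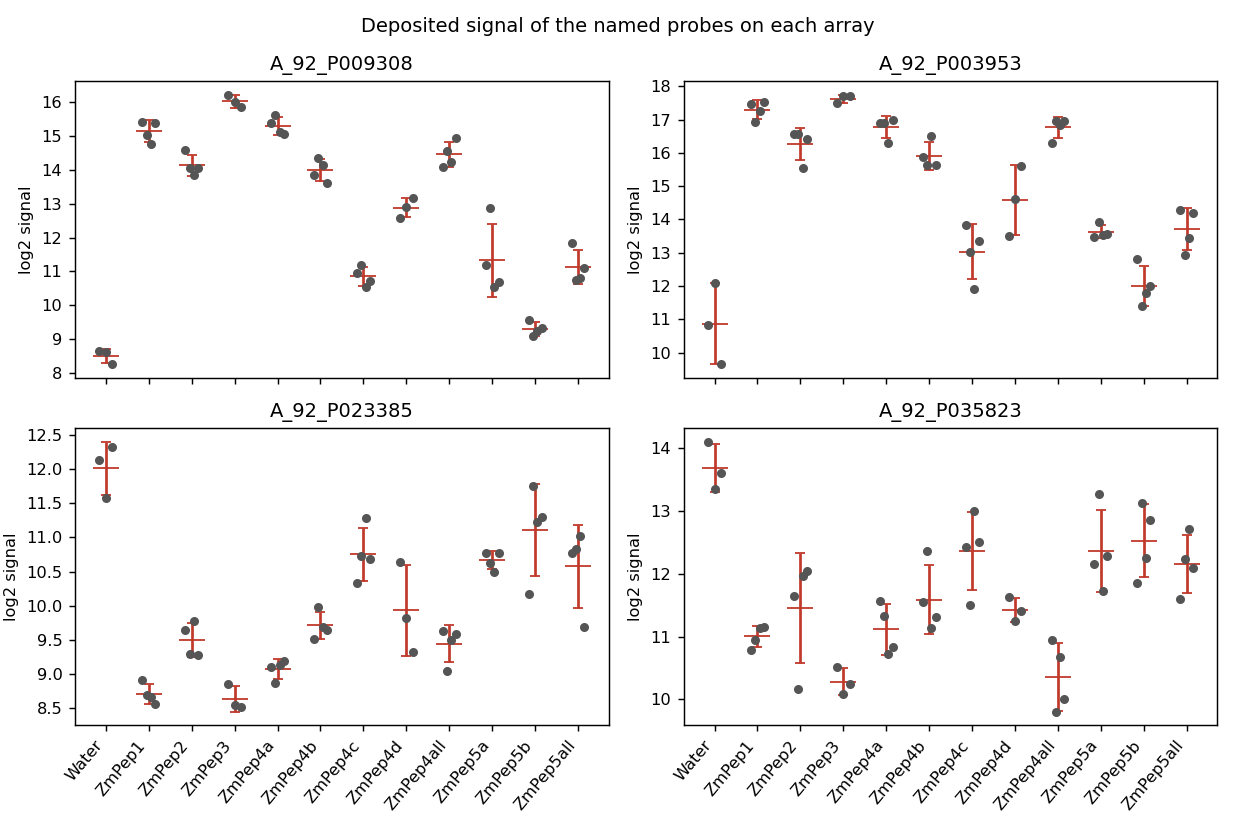
Deposited log2 signal of the 4 named probes on each of the 45 arrays (dots), by group, with the group mean (wide red mark) and its SD (bars). A_92_P009308 averages 8.51 in water and 16.02 in ZmPep3, while A_92_P023385 averages 12.0 in water and 8.64 in ZmPep3.

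Probes past the threshold against water after full quantile normalization numbered 14221 in ZmPep1 (7127 higher, 7094 lower), 14090 in ZmPep3 (7042 and 7048), 12527 in ZmPep4all (6079 and 6448), 11807 in ZmPep4a (5727 and 6080), 8464 in ZmPep4b (4143 and 4321), 8439 in ZmPep4d (3797 and 4642) and 7828 in ZmPep2 (3484 and 4344). Fewer passed in ZmPep5all, with 3326 (1806 higher, 1520 lower), in ZmPep5a, with 3030 (1108 and 1922), in ZmPep4c, with 1952 (933 and 1019), and in ZmPep5b, with 215 (76 and 139). Changes of at least 2-fold were called at 2414 probes in ZmPep3 (1029 higher, 1385 lower) and 1629 in ZmPep1 (742 and 887), against 172 in ZmPep5all (144 and 28), 110 in ZmPep5a (84 and 26), 108 in ZmPep4c (96 and 12) and 13 in ZmPep5b (6 and 7). As deposited the same calls were 1157 higher and 1092 lower in ZmPep3, 703 and 1028 in ZmPep1, 144 and 18 in ZmPep5all, 64 and 58 in ZmPep5a, 43 and 114 in ZmPep4c, and 13 and 115 in ZmPep5b, so among these the net direction turned in ZmPep3 and ZmPep4c. It also turned in ZmPep2, from 410 higher and 301 lower after full quantile normalization to 300 and 676 as deposited. The same held in ZmPep4b (413 and 308 to 369 and 447) and ZmPep4d (343 and 140 to 215 and 531), but not in ZmPep4a or ZmPep4all.

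The deposited values gave far larger and mostly one-sided counts. They were 32367 in ZmPep1 (5146 higher, 27221 lower), 33890 in ZmPep2 (1412 and 32478), 33640 in ZmPep4a (4065 and 29575), 32376 in ZmPep4b (3261 and 29115), 35152 in ZmPep4c (244 and 34908), 34999 in ZmPep4d (951 and 34048), 34163 in ZmPep4all (2726 and 31437), 21707 in ZmPep5a (410 and 21297) and 34036 in ZmPep5b (50 and 33986). The excess lay on the higher side in ZmPep3, with 33276 (28879 higher, 4397 lower), and in ZmPep5all, with 22811 (19297 and 3514). With arrays centred on their medians the higher and lower calls were 10454 and 18350 in ZmPep1, 8219 and 16495 in ZmPep2, 11813 and 9045 in ZmPep3, 10536 and 17180 in ZmPep4a, 10168 and 16330 in ZmPep4b, and 698 and 3169 in ZmPep4c. In the other groups they were 6436 and 14979 in ZmPep4d, 8871 and 17694 in ZmPep4all, 575 and 2491 in ZmPep5a, 6542 and 13749 in ZmPep5b, and 3947 and 7261 in ZmPep5all. The net direction of the deposited calls matched the sign of the shift in the lower quartile in 11 of 11 peptide groups.

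Single arrays moved some of the smaller counts after full quantile normalization by more than 1.5 times. ZmPep5b had 60 probes without its replicate 1, 549 without its replicate 2, 131 without its replicate 3, 95 without its replicate 4 and 65 without water replicate 3. It had 19 when only ZmPep5b and water entered the fit. ZmPep4c had 819, 1206 and 506 without water replicates 1, 2 and 3, and 789 and 1156 without its own replicates 2 and 4. ZmPep5a had 1463 and 1471 without water replicates 1 and 3. ZmPep5all had 1882 and 1634 without the same water replicates and 2192 and 1934 without its own replicates 1 and 4.

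**Figure D3:**
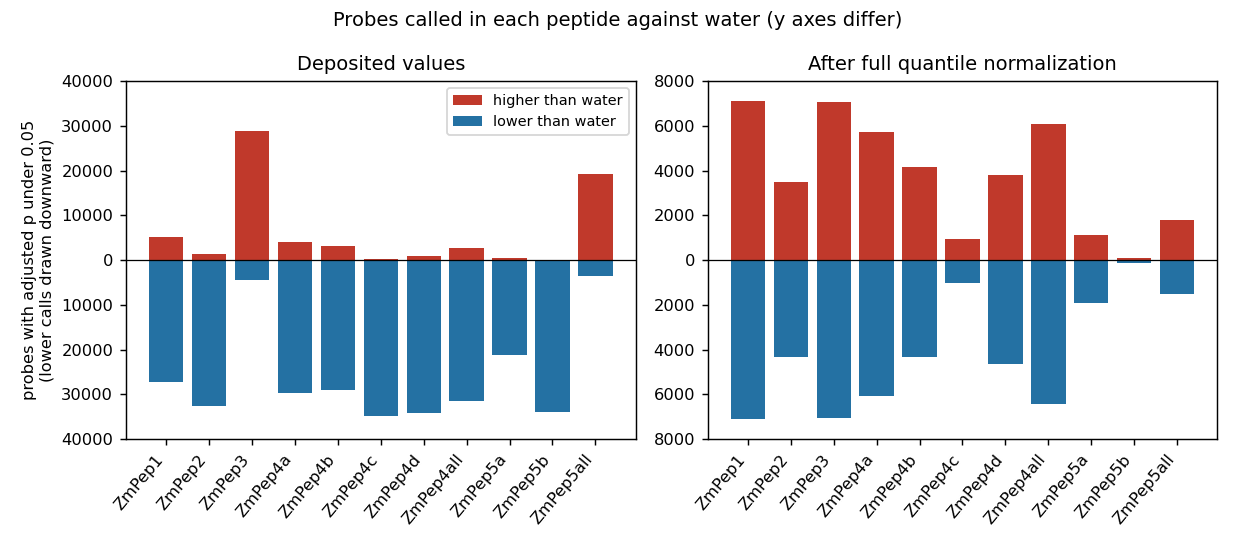
Number of probes with an adjusted p under 0.05 against water in each peptide group, higher drawn upward and lower drawn downward, in the deposited values (left) and after full quantile normalization (right); the vertical scales differ. On the left most calls of each group are in 1 direction, for example 27221 of 32367 lower in ZmPep1, while on the right the split ranges from 7042 higher and 7048 lower in ZmPep3 to 76 higher and 139 lower in ZmPep5b.

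Differences among the 11 peptide groups were tested without the water arrays in the contrast. The moderated F-test found 24113 probes that differed after full quantile normalization and 41078 as deposited. All 4 named probes differed among the peptides after full quantile normalization, with adjusted p = 2e-19 for A_92_P009308, 2.76e-14 for A_92_P003953, 9.71e-12 for A_92_P023385 and 1.94e-07 for A_92_P035823.

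ZmPep1, ZmPep2 and ZmPep3 were compared with each other, all at 5 µM and 12 h. A_92_P009308 was lower in ZmPep2 than in ZmPep3, with a log2 difference of -1.59 (95% interval -2.25 to -0.92, adjusted p = 0.000319), and A_92_P023385 was higher in ZmPep2 by 1.22 (interval 0.64 to 1.79, adjusted p = 0.0014). Between ZmPep1 and ZmPep3 no named probe passed the test after full quantile normalization: the difference at A_92_P003953 was -0.22 (interval -1.12 to 0.68) and at A_92_P009308 -0.79 (interval -1.45 to -0.13, adjusted p = 0.119; 0.0134 as deposited). Between ZmPep1 and ZmPep2, A_92_P023385 differed by -0.93 (adjusted p = 0.0134).

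Over all probes after full quantile normalization, 9600 differed between ZmPep2 and ZmPep3 (4510 higher and 5090 lower in ZmPep2), 6669 between ZmPep1 and ZmPep2 (3814 higher and 2855 lower in ZmPep1) and 4675 between ZmPep1 and ZmPep3 (2367 higher and 2308 lower in ZmPep1). At least 2-fold differences numbered 670 (369 and 301), 115 (103 and 12) and 152 (65 and 87) in these pairs, and 10502 (154 and 10348), 262 (258 and 4) and 964 (49 and 915) as deposited. The deposited values gave 36531 (1334 and 35197), 20639 (19854 and 785) and 32247 (1728 and 30519), and median centring gave 12930 and 17821, 5113 and 3409, and 14209 and 17053. The count between ZmPep1 and ZmPep3 after full quantile normalization was 2636 and 2576 without ZmPep3 replicates 2 and 3.

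Among the lettered ZmPep4 peptides, ZmPep4a and ZmPep4c were the furthest apart. A_92_P009308 was higher in ZmPep4a than in ZmPep4c by 4.001 log2 units (interval 3.39 to 4.61, adjusted p = 7.07e-13), than in ZmPep4d by 2.09 (interval 1.42 to 2.75, adjusted p = 1.2e-05) and than in ZmPep4b by 1.24 (interval 0.63 to 1.85, adjusted p = 0.00739). A_92_P003953 was higher in ZmPep4a than in ZmPep4c by 3.29 (adjusted p = 5.45e-08), and A_92_P023385 and A_92_P035823 were lower there, with log2 differences of -1.95 (adjusted p = 2.46e-07) and -1.62 (adjusted p = 0.000447). Between ZmPep4b and ZmPep4d no named probe passed the test after full quantile normalization. The difference at A_92_P009308 was 0.85 (interval 0.19 to 1.51, adjusted p = 0.118; 0.00953 as deposited) and at A_92_P003953 1.07 (interval 0.17 to 1.97, adjusted p = 0.15; 0.0198 as deposited).

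The probes that differed after full quantile normalization numbered 14107 between ZmPep4a and ZmPep4c (7196 higher and 6911 lower in ZmPep4a), 10840 between ZmPep4b and ZmPep4c (5801 and 5039), 10220 between ZmPep4a and ZmPep4d (5318 and 4902), 3250 between ZmPep4a and ZmPep4b (1575 and 1675), 3188 between ZmPep4c and ZmPep4d (1455 and 1733) and 2292 between ZmPep4b and ZmPep4d (1213 and 1079). At least 2-fold differences numbered 1097 (553 and 544), 372 (191 and 181), 342 (204 and 138), 79 (63 and 16), 94 (8 and 86) and 36 (14 and 22), and as deposited 1268 (1014 and 254), 507 (451 and 56), 457 (407 and 50), 107 (85 and 22), 130 (11 and 119) and 63 (49 and 14). In the same order the deposited values gave 30879 (10407 and 20472), 29404 (10312 and 19092), 15159 (12256 and 2903), 5093 (2064 and 3029), 24217 (20824 and 3393) and 12528 (11800 and 728), and median centring gave 12427 and 15383, 12239 and 14061, 9018 and 6063, 2323 and 2287, 8492 and 6794, and 6039 and 2089.

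Several of these counts rested on single arrays. Between ZmPep4b and ZmPep4d, 419, 1250 and 3446 probes passed after full quantile normalization without ZmPep4d replicates 1, 2 and 3, and 872 and 1393 without ZmPep4b replicates 3 and 4. The deposited count of that pair was 8219 without ZmPep4d replicate 1. Between ZmPep4c and ZmPep4d the count was 1640 without ZmPep4c replicate 3, 1994 without ZmPep4d replicate 2 and 1302 without ZmPep4d replicate 3. Between ZmPep4a and ZmPep4d it was 6554 without ZmPep4d replicate 1. Between ZmPep4a and ZmPep4b it was 1993 without ZmPep4a replicate 2 and 2022 without ZmPep4b replicate 4, and the deposited counts were 3075 and 3256 without the same arrays.

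ZmPep5a and ZmPep5b differed at both rising probes. A_92_P009308 was higher in ZmPep5a by 1.98 log2 units (interval 1.37 to 2.596, adjusted p = 9.82e-05) and A_92_P003953 by 1.61 (interval 0.77 to 2.44, adjusted p = 0.0155). At A_92_P009308 the ZmPep5a arrays read 10.62 to 12.95 after full quantile normalization, all above the ZmPep5b arrays at 9.21 to 9.68. The size of that difference leaned on ZmPep5a replicate 2, the array at 12.95. Its interval uses 1 spread over all groups. The falling probes did not pass, with -0.47 (interval -1.003 to 0.07) at A_92_P023385 and -0.18 (interval -0.91 to 0.55) at A_92_P035823. In all, 2239 probes differed after full quantile normalization, 958 higher and 1281 lower in ZmPep5a, and 42 of them by at least 2-fold, 40 higher and 2 lower. The deposited values gave 27745 (26490 and 1255), 92 of them by at least 2-fold (82 and 10), and median centring 13645 and 9853. Without ZmPep5a replicates 1 and 2 the count after full quantile normalization was 1459 and 1240, and without ZmPep5b replicates 3 and 4 it was 1242 and 1355.

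The groups called ZmPep4all and ZmPep5all were set against the mean of their lettered groups. A_92_P009308 and A_92_P003953 were higher in ZmPep4all than in the mean of ZmPep4a to ZmPep4d, by 1.17 (interval 0.69 to 1.66, adjusted p = 0.000669) and 1.73 (interval 1.06 to 2.39, adjusted p = 0.000282) log2 units, and A_92_P035823 was lower, with a log2 difference of -1.25 (interval -1.83 to -0.68, adjusted p = 0.00196). The difference at A_92_P023385 was -0.44 (interval -0.86 to -0.01, adjusted p = 0.157). The lettered mean includes ZmPep4c, where the changes were small. ZmPep4a alone averaged 15.1 at A_92_P009308, above 14.4 in ZmPep4all, and 16.6 at A_92_P003953, below 16.8 in ZmPep4all. ZmPep4all was not tested against ZmPep4a alone. In ZmPep5all no named probe passed the test against the mean of ZmPep5a and ZmPep5b after full quantile normalization. The difference was 0.70 (interval 0.17 to 1.23, adjusted p = 0.12, and 0.00493 as deposited) at A_92_P009308. At A_92_P003953 it was 0.80 (interval 0.08 to 1.52, adjusted p = 0.207, and 0.0205 as deposited). These intervals are not adjusted over probes and lie above 0, so a difference is not excluded at these probes. The probes past the threshold numbered 6911 for ZmPep4all (3563 higher, 3348 lower) and 2057 for ZmPep5all (1363 and 694), 67 (46 and 21) and 24 (22 and 2) of them by at least 2-fold, beside 70 (45 and 25) and 67 (66 and 1) as deposited. The deposited values gave 9028 (3436 and 5592) and 32249 (32105 and 144), and median centring gave 3789 and 4486, and 15802 and 12170. The count for ZmPep4all was 4519 and 4516 without its replicates 3 and 4 (5969 as deposited without replicate 3), and that for ZmPep5all was 1024 without its replicate 1.

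**Figure D4:**
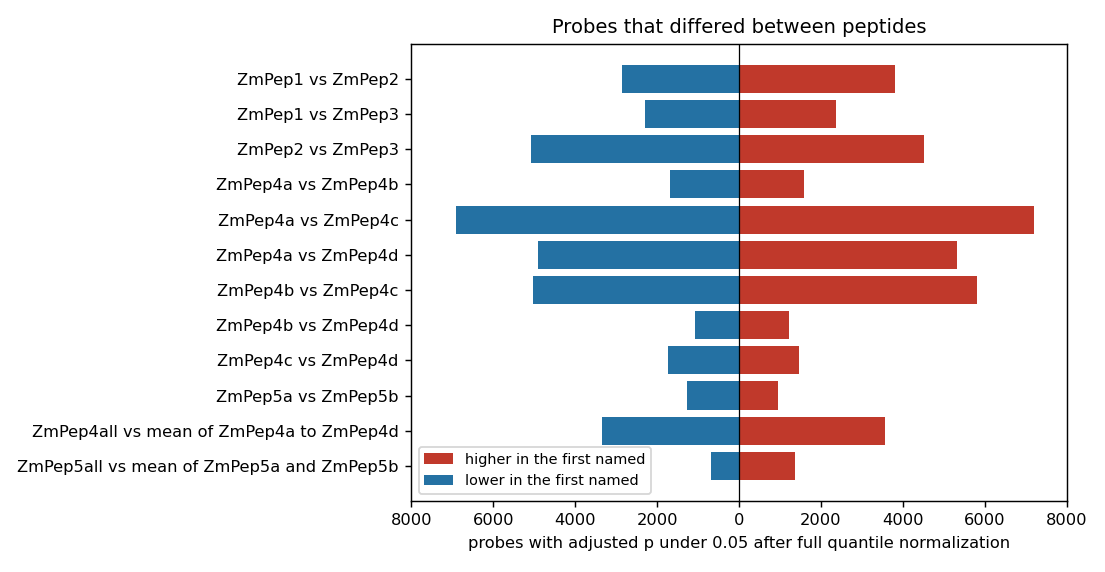
Number of probes with an adjusted p under 0.05 in each comparison between peptides after full quantile normalization, higher in the first named group to the right and lower to the left. The longest bars belong to ZmPep4a against ZmPep4c, with 14107 probes, and the shortest to ZmPep5all against the mean of its lettered groups, with 2057.

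The last comparison asked which probes moved the same way in all peptides. In total 33 probes were called in the same direction in all 11 peptide groups after full quantile normalization, 12 higher and 21 lower, and 385 in the 10 groups other than ZmPep5b, 188 higher and 197 lower. The deposited values gave 1412 in all 11, 16 higher and 1396 lower, and 1621 in the 10 groups, 115 higher and 1506 lower. In all 11, arrays centred on their medians gave 86 higher and 94 lower. In 20 simulations of unchanged groups against the same water arrays no probe was shared by all 11, but unchanged groups have few calls to share (at most 1 probe in a comparison), so this 0 sets no scale for groups with many calls. Across probes, fold changes of pairs of peptides correlated between 0.379 (ZmPep4a with ZmPep5b) and 0.947 (ZmPep3 with ZmPep4a), with a median of 0.737, beside 0.501 to 0.575 for the simulated groups. As deposited they ran from -0.0760 (ZmPep5b with ZmPep5all) to 0.940 (ZmPep1 with ZmPep4all), with a median of 0.621, so not every pair was positively correlated there. The pairs share the water arrays. The covariance of the same fold changes ran from 0.0168 to 0.213, beside a simulated mean of 0.00684, and as deposited from -0.00390 to 0.207, beside 0.00702. ZmPep1 and ZmPep3 shared 4868 higher and 5517 lower probes, where independent lists of those sizes would share 1194 and 1189.5, and 9 were called in opposite directions. As deposited this pair shared 4593 and 3795, beside 3535.5 and 2847.5, with 19601 in opposite directions. ZmPep4a and ZmPep5b, the pair with the lowest correlation after full quantile normalization, shared 27 and 86 there, beside 10.4 and 20.1, with 27 in opposite directions, and as deposited 30 and 27503, beside 4.8 and 23912.5, with 1618 in opposite directions.

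The 3 water arrays could not be divided into parts of at least 2, so part of the sharing, and of its excess over independent lists, may come from the shared controls. The 33 shared probes became 100, 132 and 18 without water replicates 1, 2 and 3, and 1, 57, 2 and 4 without the arrays of replicate numbers 1, 2, 3 and 4; the deposited count became 779 and 926 without numbers 1 and 3.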

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

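The tests in this part were all chosen only after the results were seen. In the 9 groups with 4 arrays, 6 measures were looked at (the signals of the 4 named probes, the lower quartile and the first principal component), which makes 54 sets of 4 values. In 4 of the 54 sets, 1 array was set apart from the rest by its gap relative to the range. Chance alone sets apart about 1 in 20 sets of independent, normally distributed values, but these values are not all independent. The arrays of a group share 1 distribution, which ties their lower quartiles. At A_92_P003953, replicates 1 and 2 read the same value in ZmPep2 (16.5601) and in ZmPep4a (16.9087). The rate of 1 in 20 is therefore no yardstick here. Probe A_92_P003953 read 15.5 (log2) on ZmPep2 replicate 3, below 16.4 to 16.6 on the other ZmPep2 arrays. The same probe read 16.3 on ZmPep4a replicate 3, below 16.9 to 17.0 on the others. The lower quartile of ZmPep2 replicate 2 was 6.327, below 6.337 to 6.339 on the others. On the first principal component, ZmPep4c replicate 3 scored -43.1, below -30.0 to -28.1 on the others.

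Most probes were called lower than water in the deposited values. The groups did differ in distribution after the authors' normalization, and such offsets alone can give many calls. In the simulated ZmPep1 comparison mapped to the deposited distributions, 23629 of 23817 called probes had not been changed. Whether the offsets came from the authors' normalization stays open. Of the lower calls of the peptides together, 17.2% were called lower again after full quantile normalization, and the net direction followed the lower quartile in 11 of 11 groups. Full quantile normalization removes a shift of the whole distribution whatever its origin. Neither value therefore tells an origin in the normalization apart from a general fall of transcript levels wherever a peptide changed many probes. That fall stays open too, but the deposited shifts were not alike. The 95th percentile lay above water in ZmPep1, ZmPep4a and ZmPep4b, by 0.052, 0.047 and 0.037 log2 units, though their lower quartiles lay below. Those groups thus show no fall of all levels as deposited. In ZmPep2, ZmPep4d and ZmPep4all both measures lay below water. The lower quartile of ZmPep5b, with 215 probes after full quantile normalization, lay 0.579 below water. That of ZmPep3, with 14090 probes, lay 0.406 log2 units above it. The origin of these offsets was not tested and values before normalization were not used here. The offsets therefore decide neither origin.

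ZmPep5b had the fewest calls against water after full quantile normalization. Whether the spread between its arrays played a part cannot be told from the SDs of the groups. Its median SD over probes was 0.798 times that of ZmPep2, which had 7828 calls, so a larger SD did not preclude many calls there. ZmPep2 had the largest SD of all groups. ZmPep4a, ZmPep4c and ZmPep4d also lay above the 0.0786 of ZmPep5b, while the other groups lay below it, among them ZmPep1 (0.0721) and ZmPep3 (0.0681). The fit used 1 spread per probe over all groups, so these SDs describe the arrays and not the error behind each count. A small response of the same kind as to ZmPep1 stays open: with no arrays in common, the correlation across probes of ZmPep5b minus water with ZmPep1 minus another peptide was 0.0514 to 0.212 for 7 peptides, and -0.127 and -0.207 for ZmPep3 and ZmPep4all. A partner with a large change of its own takes much of the ZmPep1 change away (slopes on it, measured from ZmPep5b, were 0.996 in ZmPep3, 0.730 in ZmPep4all and 0.718 in ZmPep4a), so this test decides nothing. The counts of ZmPep5b without single arrays, from 60 without its replicate 1 to 549 without its replicate 2, leave its size uncertain as well.

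The 2 probes with the largest fall in the peptides together, with log2 fold changes of -3.19 and -3.03, had values of 15.3 and 14.6 on water replicate 2 and of 6.84 to 6.94 on the other water arrays. Without that array their log2 fold changes were -0.389 and -0.451, so most of the size of these falls rested on the bright signal on that array alone. On water replicate 3, 38 probes lay more than 2 log2 units above both other water arrays, beside 6 on replicate 2 and 0 on replicate 1. No biological explanation was tested for this pattern.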

How the results depend on the processing

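The second set of values below, after full quantile normalization with further changes on top, was chosen only after the results were seen; the settings themselves were planned. No call of a named probe in the peptides together changed direction or side of the threshold under any setting run. The net direction of counts, higher against lower, did turn: of 25 deposited counts with a direction, in 8 after full quantile normalization, 2 with arrays centred on their medians (ZmPep5all to 3947 higher and 7261 lower, ZmPep4a against ZmPep4b to 2323 and 2287), 4 without the dimmer 50% of the probes and 7 with a fold minimum. After full quantile normalization it turned in 13 of 25 with a fold minimum, 6 without the dimmer probes, 8 of 23 with only the groups compared in the fit and 7 when arrays were left out. It turned in 0 with the replicate block or the variance trend. Of the alternatives fixed before the data were examined, all 48 arrays, all 48 with array weights and the other deposited table were not run, because the 3 removed arrays hold no values and the 2 tables are equal; the gene lists were not run for lack of gene names. The precision of dim probes is limited by signal over background, which is not given in the sources used here. With the replicate block, no count moved by over 1.5 times: the peptides together had 33241 probes as deposited and 9920 after full quantile normalization. The labels do not say that a number marks a shared batch. Over 232 pairs of arrays with the same number the mean correlation of deviations was 0.0456, beside -0.0150 for different numbers. The same-number values ran from -0.383 to 0.443, with 80 pairs over 0.1. Of 45 arrays, 24 correlated best with their own number, more than an even spread over the replicate numbers would give. Some structure shared by number may therefore be present, and its origin was not tested. The variance trend with robust moderation moved no count by over 1.5 times either. For the counts below that moved further, the cause was not tested, except that a fold minimum lowers a count by construction. A smaller set of probes caps the count, but it was fitted and adjusted anew, so calls among the kept probes can move either way.

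Full quantile normalization took the deposited counts to 9868 for the peptides together, 14221 for ZmPep1, 7828 for ZmPep2, 14090 for ZmPep3, 11807 for ZmPep4a and 8464 for ZmPep4b. It gave 1952 for ZmPep4c, 8439 for ZmPep4d, 12527 for ZmPep4all, 3030 for ZmPep5a, 215 for ZmPep5b and 3326 for ZmPep5all. The same step gave 24113 for the test among peptides, 6669 for ZmPep1 against ZmPep2, 4675 for ZmPep1 against ZmPep3, 9600 for ZmPep2 against ZmPep3, 3250 for ZmPep4a against ZmPep4b and 14107 for ZmPep4a against ZmPep4c. Counts were also 10840 for ZmPep4b against ZmPep4c, 2292 for ZmPep4b against ZmPep4d, 3188 for ZmPep4c against ZmPep4d, 2239 for ZmPep5a against ZmPep5b, 2057 for ZmPep5all against its lettered mean and 33 for the shared probes. Centring on medians gave 21334 for the peptides together, 20858 for ZmPep3, 3867 for ZmPep4c, 21415 for ZmPep4d, 3066 for ZmPep5a and 20291 for ZmPep5b. Centring also gave 11208 for ZmPep5all, 8522 for ZmPep1 against ZmPep2, 8128 for ZmPep4b against ZmPep4d, 15286 for ZmPep4c against ZmPep4d and 180 for the shared probes. Leaving out the dimmer 50% of the probes left 12259 for the peptides together, 12139 for ZmPep1, 12710 for ZmPep2, 12846 for ZmPep3, 12535 for ZmPep4a and 10896 for ZmPep4b. Among the brighter probes there were 14776 for ZmPep4c, 13972 for ZmPep4d, 13239 for ZmPep4all, 7959 for ZmPep5a, 12470 for ZmPep5b and 3895 for ZmPep5all. It also left 20105 for the test among peptides, 8932 for ZmPep1 against ZmPep2, 10486 for ZmPep1 against ZmPep3, 15335 for ZmPep2 against ZmPep3, 13450 for ZmPep4a against ZmPep4c and 12292 for ZmPep4b against ZmPep4c. There remained 4464 for ZmPep4c against ZmPep4d, 5485 for ZmPep5a against ZmPep5b, 5822 for ZmPep4all against its lettered mean and 10446 for ZmPep5all against its lettered mean. A log2 fold change of at least 1 left, as deposited, 668 for the peptides together, 1731 for ZmPep1, 976 for ZmPep2, 2249 for ZmPep3, 1674 for ZmPep4a and 816 for ZmPep4b. As deposited there were 157 for ZmPep4c, 746 for ZmPep4d, 1711 for ZmPep4all, 122 for ZmPep5a, 128 for ZmPep5b and 162 for ZmPep5all. At this minimum there were also 262 for ZmPep1 against ZmPep2, 964 for ZmPep1 against ZmPep3, 10502 for ZmPep2 against ZmPep3, 107 for ZmPep4a against ZmPep4b, 1268 for ZmPep4a against ZmPep4c and 457 for ZmPep4a against ZmPep4d. The minimum left 507 for ZmPep4b against ZmPep4c, 63 for ZmPep4b against ZmPep4d, 130 for ZmPep4c against ZmPep4d, 92 for ZmPep5a against ZmPep5b, 70 for ZmPep4all against its lettered mean and 67 for ZmPep5all against its lettered mean. As deposited there were 9 for the shared probes. With only the groups compared in the fit, the deposited counts were 13658 for ZmPep1 against ZmPep2, 2623 for ZmPep4a against ZmPep4b and 9954 for ZmPep4a against ZmPep4d.

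On fully quantile-normalized values, a log2 fold change of at least 1 left 572 for the peptides together, 1629 for ZmPep1, 711 for ZmPep2, 2414 for ZmPep3, 1489 for ZmPep4a and 721 for ZmPep4b. On these values there were 108 for ZmPep4c, 483 for ZmPep4d, 1444 for ZmPep4all, 110 for ZmPep5a, 13 for ZmPep5b and 172 for ZmPep5all. The fold minimum also left 115 for ZmPep1 against ZmPep2, 152 for ZmPep1 against ZmPep3, 670 for ZmPep2 against ZmPep3, 79 for ZmPep4a against ZmPep4b, 1097 for ZmPep4a against ZmPep4c and 342 for ZmPep4a against ZmPep4d. Others were 372 for ZmPep4b against ZmPep4c, 36 for ZmPep4b against ZmPep4d, 94 for ZmPep4c against ZmPep4d, 42 for ZmPep5a against ZmPep5b, 67 for ZmPep4all against its lettered mean and 24 for ZmPep5all against its lettered mean. On these values there were 3 for the shared probes. With only the groups compared in the fit there were 4642 for ZmPep2, 19 for ZmPep5b, 2918 for ZmPep1 against ZmPep2, 5636 for ZmPep2 against ZmPep3, 6499 for ZmPep4a against ZmPep4d, 855 for ZmPep4b against ZmPep4d and 664 for ZmPep4c against ZmPep4d. Leaving out the dimmer 50% of the probes moved none of these counts by over 1.5 times.

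Leaving out single arrays, or all arrays of a number for results over all peptides, moved these deposited counts: 779 (without replicate 1) to 1329 (without replicate 2) for the shared probes, 3075 (without ZmPep4a replicate 2) to 4913 (without ZmPep4a replicate 3) for ZmPep4a against ZmPep4b, 5969 (without ZmPep4all replicate 3) to 9392 (without ZmPep4a replicate 3) for ZmPep4all against its lettered mean and 8219 (without ZmPep4d replicate 1) to 11942 (without ZmPep4d replicate 3) for ZmPep4b against ZmPep4d. On fully quantile-normalized values the range was 6552 (without replicate 1) to 9251 (without replicate 4) for the peptides together, 506 (without water replicate 3) to 2015 (without ZmPep4c replicate 3) for ZmPep4c and 1463 (without water replicate 1) to 2596 (without ZmPep5a replicate 2) for ZmPep5a. It was 60 (without ZmPep5b replicate 1) to 549 (without ZmPep5b replicate 2) for ZmPep5b, 1634 (without water replicate 3) to 3182 (without ZmPep5all replicate 3) for ZmPep5all and 1 (without replicate 1) to 132 (without water replicate 2) for the shared probes. The range was also 2576 (without ZmPep3 replicate 3) to 4405 (without ZmPep1 replicate 4) for ZmPep1 against ZmPep3, 1993 (without ZmPep4a replicate 2) to 3051 (without ZmPep4a replicate 3) for ZmPep4a against ZmPep4b and 6554 (without ZmPep4d replicate 1) to 9785 (without ZmPep4a replicate 3) for ZmPep4a against ZmPep4d. Other ranges were 4516 (without ZmPep4all replicate 4) to 7047 (without ZmPep4a replicate 3) for ZmPep4all against its lettered mean, 419 (without ZmPep4d replicate 1) to 3446 (without ZmPep4d replicate 3) for ZmPep4b against ZmPep4d and 1302 (without ZmPep4d replicate 3) to 3054 (without ZmPep4c replicate 4) for ZmPep4c against ZmPep4d. Ranges were 1240 (without ZmPep5a replicate 2) to 2240 (without ZmPep5a replicate 3) for ZmPep5a against ZmPep5b and 1024 (without ZmPep5all replicate 1) to 1983 (without ZmPep5a replicate 1) for ZmPep5all against its lettered mean.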

Other observations

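The tests in this part were all chosen only after the results were seen. On the fully quantile-normalized values of the brighter 50% of the probes, the first principal component held 54.0% of the variance and placed the groups in an order from water to ZmPep3. Water scored -45.8 ± 2.97 (SD, n = 3). Next to it lay ZmPep5b at -38.2 ± 6.02, ZmPep4c at -32.7 ± 6.93, ZmPep5a at -26.7 ± 1.65 and ZmPep5all at -24.2 ± 6.25. ZmPep4d scored -4.47 ± 8.55, ZmPep2 9.62 ± 4.43 and ZmPep4b 11.2 ± 4.68. ZmPep4all scored 26.4 ± 6.75, ZmPep1 34.4 ± 6.39, ZmPep4a 34.8 ± 2.54 and ZmPep3 57.3 ± 2.21, each SD over the 3 or 4 arrays of the group. The component with the next largest share held 6.91%. The order was not tested.

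A hypothesis from this order is that the peptides may bring about 1 response at different sizes. It came from the principal component of these same arrays, so the values that follow look at the same axis again and do not decide it. They are correlations across probes of each peptide minus ZmPep5b with ZmPep1 minus water, which share no arrays: 0.907 in ZmPep4all, 0.870 in ZmPep3, 0.793 in ZmPep2, 0.792 in ZmPep4a, 0.787 in ZmPep4b, 0.698 in ZmPep4d, 0.434 in ZmPep5all, 0.429 in ZmPep5a and 0.257 in ZmPep4c. In 8 of 9 peptides the value was above the largest size, 0.412, seen in 24 splits of the arrays within a group, a bound that speaks only to whether some axis is common and not to whether the response is 1 and the same. The slope on the ZmPep1 change ran from 0.0875 in ZmPep4c to 0.996 in ZmPep3.

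Other splits of the same arrays into groups of the same sizes were refitted, 35 for most pairs of groups and 100 for contrasts of more groups. In the deposited values these counts say nothing about chance, because the arrays of a group share 1 distribution and only the real arrangement lines up with the offsets between groups. There, only 1 split, the real arrangement, gave as many probes in the comparisons listed next, and the highest other gave 31984 beside 33122 for the peptides together, 29143 beside 32367 for ZmPep1, 31369 beside 33890 for ZmPep2, 30736 beside 33640 for ZmPep4a, 29093 beside 32376 for ZmPep4b and 30184 beside 35152 for ZmPep4c. It gave 31723 beside 34163 for ZmPep4all, 8080 beside 21707 for ZmPep5a, 29849 beside 34036 for ZmPep5b, 14977 beside 22811 for ZmPep5all, 21963 beside 41078 for the test among peptides and 5193 beside 20639 for ZmPep1 against ZmPep2. Other highest counts were 29584 beside 32247 for ZmPep1 against ZmPep3, 33815 beside 36531 for ZmPep2 against ZmPep3, 284 beside 5093 for ZmPep4a against ZmPep4b, 11273 beside 30879 for ZmPep4a against ZmPep4c, 10207 beside 15159 for ZmPep4a against ZmPep4d and 6904 beside 29404 for ZmPep4b against ZmPep4c. The highest were 6851 beside 12528 for ZmPep4b against ZmPep4d, 18420 beside 24217 for ZmPep4c against ZmPep4d, 13898 beside 27745 for ZmPep5a against ZmPep5b and 28418 beside 32249 for ZmPep5all against its lettered mean. For ZmPep4all against its lettered mean, 6 of 100 deposited splits gave as many as 9028, up to 18047. The deposited counts of ZmPep3 and ZmPep4d against water, 33276 and 34999, were set against 10 splits, with 17 and 5 as the highest others.

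Full quantile normalization removes these offsets. On its values only 1 split, the real arrangement, gave as many probes in each comparison listed next. Taken singly, each such share of splits is under 0.05. No correction was made over the many comparisons, so chance is not excluded for the list as a whole. For the peptides together, the splits also mixed peptide groups that differ from each other, so that share does not measure chance. The highest other split gave 7494 beside 9868 for the peptides together, 10087 beside 14221 for ZmPep1, 7753 beside 7828 for ZmPep2, 9067 beside 11807 for ZmPep4a, 4806 beside 8464 for ZmPep4b and 864 beside 1952 for ZmPep4c. It was 10436 beside 12527 for ZmPep4all, 664 beside 3030 for ZmPep5a, 1390 beside 3326 for ZmPep5all, 2612 beside 24113 for the test among peptides, 2030 beside 6669 for ZmPep1 against ZmPep2 and 1958 beside 4675 for ZmPep1 against ZmPep3. Other splits reached 6422 beside 9600 for ZmPep2 against ZmPep3, 80 beside 3250 for ZmPep4a against ZmPep4b, 4002 beside 14107 for ZmPep4a against ZmPep4c, 5842 beside 10220 for ZmPep4a against ZmPep4d, 989 beside 10840 for ZmPep4b against ZmPep4c and 235 beside 2292 for ZmPep4b against ZmPep4d. They reached 1243 beside 3188 for ZmPep4c against ZmPep4d and 275 beside 2239 for ZmPep5a against ZmPep5b.

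For ZmPep4all against its lettered mean after full quantile normalization, 3 of 100 splits gave as many probes as the real 6911, up to 8982. For ZmPep5all against its lettered mean 2 of 100 gave as many as 2057, up to 2276. These splits mixed arrays of lettered groups that differ from each other (14107 probes between ZmPep4a and ZmPep4c, 2239 between ZmPep5a and ZmPep5b). Their shares therefore do not measure chance, and the splits decide neither count. For ZmPep5b against water after full quantile normalization, 2 of 35 splits gave as many as the real 215, up to 435, so chance cannot be excluded. ZmPep3 and ZmPep4d against water allow only 10 splits, too few for a share under 0.05: their real counts after full quantile normalization were 14090 and 8439, with 1 as the highest other in both.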
